A study of Rattus norvegicus with 21 samples.

How the data were processed

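Total RNA of rat NBTII bladder carcinoma cells and of NBTII-FGFR1 cells, treated with FGF1 for 0, 0.5, 2, 6, 24 or 48 h, was measured on 21 Affymetrix expression arrays, 1 per sample. The deposited table holds log2 signal intensities that the authors made with RMA, per the submitters' processing notes; the RMA version is not given in the sources used here. The deposited table was used as it stands, and no raw image files were analysed here. It holds 15923 probe sets. The 57 control probe sets were left out of the tests and read separately, and the other 15866 were tested without a filter on low values. By the annotation table, 12783 of these carry 1 gene symbol, 312 several and 2771 no symbol or no entry, which gives 10411 symbols. The array medians were close (6.13 to 6.22). The largest distance of an array from the mean of all arrays at any quantile was 0.245. No further normalization was applied.

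Groups were taken from the sample titles: 12 combinations of line and time, 9 with 2 arrays and 3 with 1. Replicate numbers were not used in the fit, and a block by number was an alternative. Linear models over the 12 group means were fitted with limma 3.58.1 in R 4.3.3, with 9 residual and 5.68 prior degrees of freedom. Groups with 1 array are assumed to vary like the others. P-values were adjusted by the Benjamini-Hochberg method over all 15866 probe sets within each comparison, with a threshold of 0.05. The comparisons were 2, 6, 24 and 48 h against 0 h within each line, 0.5 h against 0 h within NBTII-FGFR1 and over both lines, 48 h against 2 h within each line, the line difference at 0 h and averaged over 2 to 48 h, the line by time difference for 48 h against 2 h and, by an F test, over 2 to 48 h, and the difference between the lines' mean responses from 0 h. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.

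The 23 gene lists were written before the data were examined: immediate-early genes, FGF and ERK feedback genes, FGF receptors, desmosome, adherens and tight junctions, keratins, mesenchymal and fibroblast markers, pericellular proteolysis, DNA replication, mitosis, cell cycle inhibitors and p53 targets, growth factors and other receptor kinases, hemidesmosome and laminin-332, integrins with focal adhesion and actin, cytokines with chemokines and NF-kB targets, cholesterol synthesis, glycolysis and hypoxia response, unfolded protein and amino acid response, interferon response, ribosome biogenesis, urothelial differentiation, leukocyte markers and endothelial markers. A gene was represented by its probe set with the highest mean. Lists were tested with camera at its preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, and p-values were adjusted over the 23 lists of each comparison.

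Named genes followed a rule fixed before the data were examined. Symbols that begin with LOC or RGD, and probe sets with no or several symbols, were passed over. Named were 18 genes fixed in advance, of which 16 were measured. Per comparison, the 3 rising and 3 falling genes with the largest log2 difference were taken from those past the threshold whose arrays did not overlap. It was 6 and 6 for the line difference over 2 to 48 h and for 48 h against 2 h within each line. No overlap rule was applied to the line by time difference for 48 h against 2 h. The difference between the lines' mean responses from 0 h had none either. Per list, up to 4 members with the smallest p were named.

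The pipeline was tested on simulated data with changes planted in 100 probe sets per size. At a log2 change of 1 it recovered 84% for NBTII-FGFR1 at 6 h, 67% for NBTII at 6 h, 67% for NBTII-FGFR1 at 0.5 h and 100% for the line difference over 2 to 48 h, and at a log2 change of 2 it recovered 100%, 97%, 95% and 99%. Of the calls, 5.64% to 6.36% were false. The simulated noise was independent between arrays and genes and equal in all groups. These rates therefore do not cover arrays that deviate together, correlated genes or groups of unequal spread. For the list test, 23 sets of randomly drawn genes were simulated in place of the written lists. Of these, 1 was raised by 0.5 and was called, and 0 unchanged sets were called. As the simulated genes varied independently, this does not test whether the preset correlation suits the written lists.

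The alternatives chosen before the data were examined were leaving out the probe sets below the median level, a block by replicate number, only the arrays a comparison is about, repeated quantile normalization, eBayes with trend and robust set, array weights, each of 18 arrays left out in turn, the 2 other list tests, the mean of all probe sets of a gene, and Spearman correlation. Only arrays of the groups with 2 arrays were left out in turn. The lone NBTII 0 h array and the 0.5 h arrays therefore stayed in all 18 fits, which do not test them. Leaving out both doubted arrays, the library labelled NBTII-FGFR1 0 h replicate 1 and NBTII-FGFR1 2 h replicate 1, was added after the data were seen.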

Results

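Gene expression was profiled in NBTII, an epithelial rat bladder carcinoma line, and in NBTII-FGFR1, the same line transfected with FGF receptor 1, along a time course of FGF1. As no array after 0 h lacks FGF1, time, heparin and handling are not separated from it. The ligand was given at 20 ng/ml with heparin, and the series places the time course in the epithelial to mesenchymal transition of carcinoma cells. The 21 Affymetrix arrays, 1 sample each, fell into 12 groups of line and time (0, 0.5, 2, 6, 24 and 48 h). In 9 groups there were 2 arrays, and NBTII at 0 h and both lines at 0.5 h had 1 array each, whose spread is taken from the other groups. The titles were followed here: the series text says that control cells had no duplicate, but 2 titles name NBTII-FGFR1 at 0 h. Array medians lay between 6.13 and 6.22 on the log2 scale, and the 2 arrays of a group correlated at r = 0.988 (NBTII-FGFR1 2 h) to 0.997 (NBTII-FGFR1 48 h) across probe sets. The number of arrays limits the precision. Since the labels do not say whether replicates came from separate cultures, the p-values measure only the spread between these samples, which may be technical. Values below are log2 differences ± SE of the common limma fit, and a gene "rose", "fell" or "differed" where its adjusted p passed 0.05 over the 15866 probe sets tested. The table has no detection calls. A level below the lower quartile of an array (4.36 to 4.54) was not shown to exceed background, and a difference from it is best read as a lower bound. Gene lists carry the adjusted p of camera with its preset correlation, and 21 of the 168 list calls held with an estimated one.

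Fgfr1 (1387498_a_at), the transfected receptor gene, set the lines apart in nearly every array. Over 2 to 48 h it lay between 3.58 and 4.05 in the 8 NBTII arrays and between 4.56 and 7.58 in the 8 NBTII-FGFR1 arrays, and it read 7.50 in NBTII-FGFR1 at 0.5 h. At 0 h it read 3.97 in NBTII, 5.92 in NBTII-FGFR1 replicate 2 and 3.57 in the library labelled NBTII-FGFR1 0 h replicate 1, which is 0.01 below the lowest of the 8 NBTII values. Igfbp5, a secreted insulin-like growth factor binding protein that was lower in NBTII-FGFR1, read 7.51 in that library against 4.39 in replicate 2 and 8.63 in NBTII at 0 h. Over 115 probe sets that parted the lines in each of the 16 arrays of 2 to 48 h, its median position was -0.00 on a scale from the NBTII mean at 0 to the NBTII-FGFR1 mean at 1, and 105 of the 115 lay nearer to NBTII. Replicate 2 at 0 h lay at 0.77 and NBTII at 0 h at -0.20. In Fos, a transcription factor gene that growth factors induce within minutes, the library labelled replicate 1 (9.52) lay near replicate 2 (9.03) and far from NBTII at 0 h (4.90). Each NBTII-FGFR1 difference from 0 h therefore averages over this library as labelled. The 2 h arrays did not all pair by group. NBTII-FGFR1 2 h replicate 1 correlated best with an 0.5 h array (r = 0.990), above its own partner (r = 0.988). That partner, replicate 2, and NBTII 2 h replicate 2 correlated best with each other (r = 0.993), above the 2 NBTII arrays of 2 h (r = 0.992). The library labelled NBTII-FGFR1 0 h replicate 1 and NBTII-FGFR1 2 h replicate 1 are called the doubted arrays below. The bacterial poly-A spikes, added before labelling, read 6.49 to 7.07 in the 3 arrays of 0 h and 5.58 to 6.02 in the 18 later arrays, so every difference from 0 h sets these 2 ranges against each other, and 48 h against 2 h does not.

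**Figure D1:**
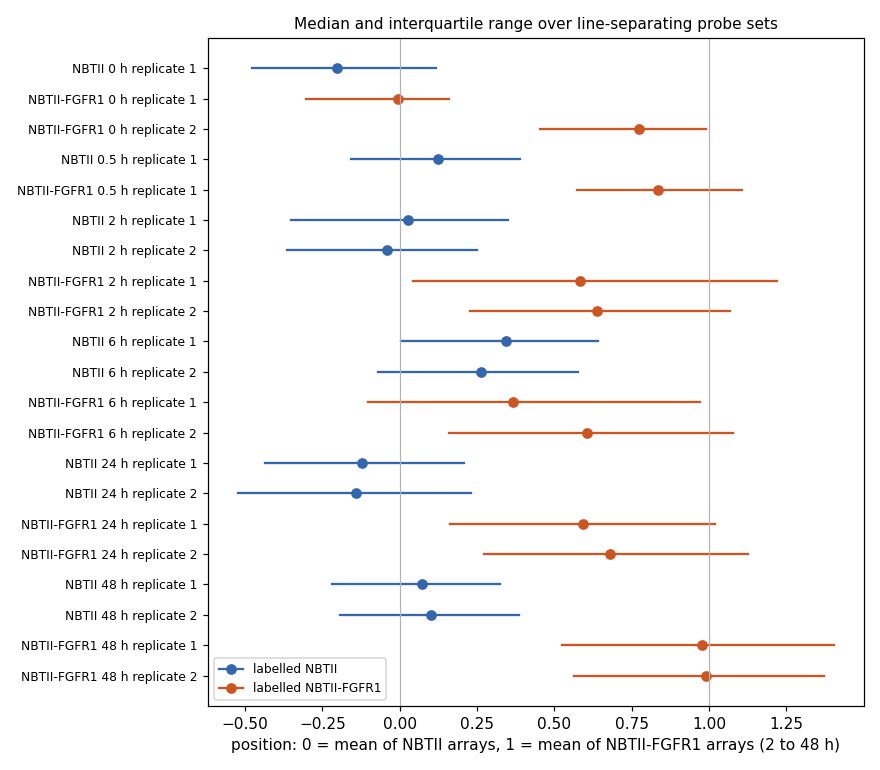
Position of each of the 21 arrays between the 2 lines: points are medians and bars interquartile ranges over probe sets that part the lines at 2 to 48 h (x axis, no unit; 0 is the NBTII mean and 1 the NBTII-FGFR1 mean), with separators for each 2 to 48 h array taken from the other times. The library labelled NBTII-FGFR1 0 h replicate 1 lies at -0.00, among the NBTII arrays (-0.20 to 0.34), and the other NBTII-FGFR1 arrays lie between 0.37 and 0.99.

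After 0.5 h of FGF1, averaged over both lines with 1 array per line, immediate-early genes had risen. Of 30 measured, 19 rose and 0 fell (20 and 1 adjusted over the list alone). Their median was 1.47 and the list's adjusted p of 6.7e-32 held with an estimated correlation (adjusted p = 0.0015). Fosb, an AP-1 subunit, rose by 3.79 ± 0.19, Nr4a1, an orphan nuclear receptor, by 3.51 ± 0.25, and Zfp36, an mRNA decay factor, by 3.52 ± 0.21. Dusp1 (1368146_at), a MAP kinase phosphatase, rose by 4.32 ± 0.35, Pnrc1 (1370381_at) by 4.09 ± 0.54 and Atf3 (1369268_at), a stress-induced transcription factor, by 3.83 ± 0.52. Myh1 (-1.47 ± 0.23), Zfp386 (-1.13 ± 0.20) and Itgb3bp (-1.04 ± 0.15) fell. Of 35 cytokine, chemokine and NF-kB target genes, 7 rose and 0 fell (10 and 0 adjusted over the list alone), and the list's adjusted p was 7.9e-05 (adjusted p = 0.17 with an estimated correlation). Nfkbia, encoding the NF-kB inhibitor, rose by 3.04 ± 0.33 and Icam1, an adhesion receptor gene, by 2.73 ± 0.44. The plasminogen activator Plau (1.68 ± 0.24) and its receptor gene Plaur (1.85 ± 0.32) rose too. In NBTII, with 1 array against 1 and no test, Fos read 10.68 at 0.5 h against 4.90 at 0 h and Egr1 11.36 against 6.71. Limma called 349 probe sets over both lines (267 higher, 82 lower), 184 without the library labelled NBTII-FGFR1 0 h replicate 1, 664 without either NBTII-FGFR1 2 h array, 147 with only the arrays compared and 653 with array weights.

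In NBTII-FGFR1 alone, 0.5 h differed from 0 h at 315 probe sets, 155 higher and 160 lower. This sets 1 array against 2, of which 1 is the library labelled replicate 1, and its spread comes from other groups. Pnrc1 rose by 4.21 ± 0.71 and Dusp1 (1368147_at) by 3.68 ± 0.42, and Syncrip (1390489_at), an RNA-binding protein gene, fell by 1.67 ± 0.29. The chemokine gene Cxcl1 (1387316_at, 4.49 ± 1.06), the kallikrein gene Klk6 (-1.75 ± 0.40) and the nuclear pore gene Tpr (-1.87 ± 0.34) passed too, but lost their calls in 14, 6 and 1 of the 18 fits that left out 1 array, with adjusted p up to 0.16, 0.13 and 0.11. Immediate-early genes rose (13 of 30, 18 adjusted over the list alone, 0 fell; adjusted p = 3.5e-17, and adjusted p = 0.015 with an estimated correlation). The count of calls was 49 without the library labelled NBTII-FGFR1 0 h replicate 1, 170 without replicate 2, 502 without either 2 h array, 116 without both doubted arrays, and 626 with array weights.

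At 2 h in NBTII-FGFR1 (2 arrays against 2), genes of pericellular proteolysis and of the response to growth factors rose. Mmp13 (1388204_at), a collagenase, rose by 4.85 ± 0.52, Plaur (1387269_s_at) by 3.87 ± 0.35, the gelatinase Mmp9 (1398275_at) by 2.78 ± 0.29 and Plau (1387675_at) by 2.56 ± 0.25. Of the 32 proteolysis genes 12 rose and 0 fell, by the same counts adjusted over the list alone (adjusted p = 1.5e-08, and adjusted p = 0.012 with an estimated correlation). Of 14 FGF and ERK feedback genes, 7 rose and 0 fell (7 and 1 adjusted over the list alone; adjusted p = 5.3e-07, and adjusted p = 0.041 with an estimated correlation). Spry2 (1374864_at), a receptor kinase antagonist, rose by 1.47 ± 0.13 and the ERK phosphatase Dusp6 (1387024_at) by 0.94 ± 0.14. However, 1 of the 2 other Dusp6 probe sets was called lower. Immediate-early genes were still raised, with 19 of 30 higher and 1 lower (21 and 2 adjusted over the list alone; adjusted p = 5.9e-15, and adjusted p = 0.012 with an estimated correlation). Fosl1 (1368489_at), encoding the Fra-1 subunit of AP-1, rose by 2.30 ± 0.19. Among 42 growth factor and receptor kinase genes, 12 rose and 0 fell (12 and 1 adjusted over the list alone; adjusted p = 0.00024, and adjusted p = 0.043 with an estimated correlation). The EGF receptor ligand genes Hbegf (2.60 ± 0.30), Ereg (2.50 ± 0.39) and Areg (2.02 ± 0.29) rose. The protease gene Asprv1 (1372418_at) rose by 4.67 ± 0.40 and Pnrc1 by 4.21 ± 0.58, whereas the junction-associated Amotl2 (1389546_at) fell by 2.54 ± 0.30 and Klk6 by 2.20 ± 0.32. Limma called 836 probe sets higher and 647 lower at 2 h, 1483 in all, but 518 without the library labelled NBTII-FGFR1 0 h replicate 1, 880 without replicate 2 at 0 h, 686 without both doubted arrays, 968 with only the arrays compared and 766 with array weights.

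Other groups moved at 2 h in NBTII-FGFR1. Ribosome biogenesis genes fell, 10 of 31 with 1 higher (20 and 1 adjusted over the list alone; adjusted p = 5.3e-07, adjusted p = 0.073 with an estimated correlation). Rrs1, an assembly factor, fell by 1.36 ± 0.17 (-1.36), while Odc1, the enzyme that starts polyamine synthesis, rose by 1.18 ± 0.15. Of 20 cell cycle inhibitors and p53 targets, 7 rose and 1 fell, by the same counts adjusted over the list alone (adjusted p = 0.0037, adjusted p = 0.096 with an estimated correlation). Cdkn1a, encoding the p21 inhibitor, rose by 2.05 ± 0.31 and Mdm2 by 1.28 ± 0.17. Of 20 adherens and tight junction genes, 9 rose and 1 fell, also by the same counts adjusted over the list alone (adjusted p = 0.00038, adjusted p = 0.12 with an estimated correlation). The claudin gene Cldn4 rose by 1.87 ± 0.24. Among genes fixed beforehand, Fgfr1 (2.38 ± 0.57), the matrix gene Fn1 (1.26 ± 0.27), the E-cadherin gene Cdh1 (0.86 ± 0.25), the plakoglobin gene Jup (0.48 ± 0.13), Krt8 (0.98 ± 0.28) and Egr1 (1.70 ± 0.45) passed, but lost their calls in 2, 1, 5, 6, 3 and 3 of the 18 fits without 1 array. The adjusted p reached 0.20 for Fgfr1 (then 1.21), 0.092 for Fn1 and 0.19 for Jup without the library labelled NBTII-FGFR1 0 h replicate 1, 0.32 for Cdh1 (then 0.55) and 0.25 for Krt8 without 0 h replicate 2, and 0.15 for Egr1 without 2 h replicate 1. Krtdap, a keratinocyte differentiation gene (-2.52 ± 0.67), lost its call in 4 of those fits (adjusted p up to 0.13). Vim (1.94 ± 0.72), Dsp (0.29 ± 0.15), Fgfr2 (0.13 ± 0.29) and Snai1 (-0.09 ± 0.16) did not pass.

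By 6 h in NBTII-FGFR1 (2 arrays against 2), stromelysin and collagenase genes were among those with the largest rises and replication genes had fallen. Mmp3 (1368657_at) rose by 6.59 ± 0.44, Mmp13 by 6.40 ± 0.52, Mmp10 (1368713_at) by 6.04 ± 0.65, Mmp9 by 4.88 ± 0.29, Plau by 3.18 ± 0.25 and Plaur by 3.17 ± 0.35. The 4 metalloproteinases start from 0 h means of 3.68, 4.32, 4.14 and 3.67, below the lower quartile of every array, so their differences from 0 h are lower bounds here and at the other times. In the proteolysis list 14 of 32 rose and 0 fell (15 and 0 adjusted over the list alone; adjusted p = 7e-09, and adjusted p = 0.023 with an estimated correlation). DNA replication genes fell, 24 of 26 with 0 higher, by the same counts adjusted over the list alone (median -0.84, adjusted p = 4.1e-16, adjusted p = 0.079 with an estimated correlation). The helicase subunit gene Mcm2 (-1.32 ± 0.15) and the polymerase subunit gene Pola1 (-1.61 ± 0.18) were among them. Of 26 mitosis genes 16 fell and 1 rose (18 and 1 adjusted over the list alone; adjusted p = 7e-09, adjusted p = 0.094 with an estimated correlation). Ccnb2, a mitotic cyclin gene, changed by -1.08 ± 0.13. Ribosome biogenesis genes fell, 23 of 31 with 1 higher (25 and 1 adjusted over the list alone; adjusted p = 5.3e-11, adjusted p = 0.059 with an estimated correlation). Cad, encoding the first enzyme of pyrimidine synthesis, changed by -1.61 ± 0.16. Cholesterol synthesis genes fell, 9 of 19 with 0 higher (11 and 0 adjusted over the list alone; adjusted p = 5e-07, adjusted p = 0.38 with an estimated correlation). Dhcr7 (-1.78 ± 0.15) and Cyp51 (-1.61 ± 0.20), of the late steps of the pathway, were among these. Of 43 integrin, focal adhesion and actin genes, 17 rose and 3 fell (20 and 3 adjusted over the list alone; adjusted p = 1.8e-05, adjusted p = 0.064 with an estimated correlation). Zyx, a focal adhesion gene, rose by 2.31 ± 0.32.

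Immediate-early genes as a list no longer stood apart at 6 h in NBTII-FGFR1, with 4 of 30 higher and 4 lower, by the same counts adjusted over the list alone (median 0.00, mean -0.04, adjusted p = 0.94). Fos (1375043_at) fell by 3.17 ± 0.40 below its 0 h level, while Fosl1 (1.99 ± 0.19), Spry2 (1.72 ± 0.13) and Dusp6 (0.97 ± 0.14) stayed raised. The glutamate transporter gene Slc1a3 (1368565_at) fell by 2.76 ± 0.34, although 1 of its 2 other probe sets was called higher. Cdh1 (1.15 ± 0.25), Krt8 (1.25 ± 0.28), the desmosomal gene Dsp (-0.64 ± 0.15) and Fgfr2 (-1.02 ± 0.29) passed and lost their calls in 1, 2, 1 and 3 of the 18 fits without 1 array: adjusted p reached 0.061 for Cdh1 without 0 h replicate 2, and 0.071 for Krt8, 0.066 for Dsp and 0.17 for Fgfr2 without 6 h replicate 2. Krtdap (-2.59 ± 0.67) lost its call in 4 (adjusted p up to 0.065). Fgfr1 (0.85 ± 0.57), Jup (0.24 ± 0.13), Vim (1.35 ± 0.72), Fn1 (0.43 ± 0.27), Egr1 (-0.92 ± 0.45) and Snai1 (0.13 ± 0.16) did not pass. Limma called 3382 probe sets, 1489 higher and 1893 lower, but 1909 without the library labelled NBTII-FGFR1 0 h replicate 1 and 1898 without 6 h replicate 2.

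At 24 h in NBTII-FGFR1 (2 arrays against 2), keratin and desmosome genes were lower, and Mmp3, Mmp13 and Mmp10 stayed high. Mmp3 was above 0 h by 6.72 ± 0.44, Mmp13 by 6.68 ± 0.52, Mmp10 by 6.11 ± 0.65 and Plaur by 2.28 ± 0.35, whereas Mmp9 (0.46 ± 0.29) and Plau (0.30 ± 0.25) no longer passed. Of the 32 proteolysis genes 7 rose and 0 fell (7 and 1 adjusted over the list alone; adjusted p = 0.0032, adjusted p = 0.18 with an estimated correlation). Keratin genes fell, 7 of 13 with 0 higher (9 and 0 adjusted over the list alone; adjusted p = 8.9e-08, adjusted p = 0.10 with an estimated correlation). Krt5, of the basal epithelial layer (-1.71 ± 0.25), and Krt13 (-1.94 ± 0.29) fell. Of 7 desmosome genes 3 fell and 0 rose, by the same counts adjusted over the list alone (adjusted p = 0.0049, adjusted p = 0.23 with an estimated correlation). Dsp, encoding desmoplakin, changed by -1.36 ± 0.15. Fos fell by 3.95 ± 0.40 and Klk6 by 2.38 ± 0.32, and Fosl1 rose by 1.36 ± 0.19. Of 30 immediate-early genes 2 rose and 7 fell (2 and 10 adjusted over the list alone; adjusted p = 0.0011, adjusted p = 0.23 with an estimated correlation). Replication genes were near their 0 h level, with 0 of 26 higher and 1 lower, by the same counts adjusted over the list alone (median -0.03, adjusted p = 0.60). Vim, the mesenchymal intermediate filament gene, was higher by 3.33 ± 0.72 but missed the threshold without the library labelled NBTII-FGFR1 0 h replicate 1 (2.26, adjusted p = 0.18) and in 2 more of the 18 fits. Fgfr2 (-1.57 ± 0.29), Jup (-0.52 ± 0.13), Spry2 (0.84 ± 0.13), Dusp6 (0.74 ± 0.14) and Krtdap (-3.13 ± 0.67) lost their calls in 2, 4, 1, 2 and 3 fits, with adjusted p up to 0.096, 0.27, 0.056 and 0.13 for Fgfr2 (then -0.97), Jup, Spry2 and Krtdap without 24 h replicate 2 and 0.11 for Dusp6. Cdh1 (-0.81 ± 0.25), Egr1 (-1.45 ± 0.45), Fgfr1 (0.60 ± 0.57), Fn1 (-0.51 ± 0.27), Krt8 (-0.46 ± 0.28) and Snai1 (-0.07 ± 0.16) did not pass. The 999 calls (566 higher, 433 lower) became 183 without the library labelled NBTII-FGFR1 0 h replicate 1, 509 without replicate 2 at 0 h, 114 without 24 h replicate 2, 379 without both doubted arrays, 566 with only the arrays compared and 1715 with array weights.

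At 48 h in NBTII-FGFR1 (2 arrays against 2), protease genes and genes of the unfolded protein and amino acid response were higher, and replication, mitosis, ribosome biogenesis and keratin genes were lower. Mmp10 rose by 8.15 ± 0.65, Mmp13 by 7.97 ± 0.52, Mmp3 by 6.96 ± 0.44, the protease inhibitor gene Serpine2 by 2.72 ± 0.21 and Plaur by 2.42 ± 0.35. In the proteolysis list 13 of 32 rose and 0 fell (16 and 0 adjusted over the list alone; adjusted p = 2.6e-07, and adjusted p = 0.040 with an estimated correlation). Of 34 unfolded protein and amino acid response genes 24 rose and 0 fell (26 and 1 adjusted over the list alone; median 0.93, adjusted p = 1.2e-12, adjusted p = 0.089 with an estimated correlation). Ddit3, encoding the CHOP transcription factor, rose by 2.66 ± 0.37 and Sel1l, of the pathway that degrades misfolded proteins, by 1.78 ± 0.18. Replication genes fell, 25 of 26 with 0 higher, by the same counts adjusted over the list alone (median -0.94, adjusted p = 8.1e-17, adjusted p = 0.081 with an estimated correlation). Pole changed by -1.44 ± 0.15 and Pcna, the polymerase clamp gene, by -0.95 ± 0.11. Of 26 mitosis genes 21 fell and 0 rose (23 and 0 adjusted over the list alone; adjusted p = 2e-11, adjusted p = 0.081 with an estimated correlation). The mitotic kinase gene Aurkb changed by -1.03 ± 0.13. Ribosome biogenesis genes fell, 27 of 31 with 1 higher (28 and 1 adjusted over the list alone; adjusted p = 1.2e-12, and adjusted p = 0.040 with an estimated correlation). Fbl, a nucleolar methyltransferase gene, changed by -1.08 ± 0.13. Of 13 keratin genes 6 fell and 0 rose (7 and 0 adjusted over the list alone; adjusted p = 3e-05, adjusted p = 0.081 with an estimated correlation). Krt5 (1370863_at) changed by -3.51 ± 0.25 and Krt14 by -1.98 ± 0.13. Fos fell by 3.69 ± 0.40, and Slc1a3 by 3.46 ± 0.34, with 1 of its 2 other probe sets called higher.

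Of the other genes fixed beforehand, Fgfr2, whose epithelial splice form is the keratinocyte growth factor receptor, fell in NBTII-FGFR1 at 48 h by 2.12 ± 0.29, Dsp by 1.01 ± 0.15 and Jup by 0.92 ± 0.13. Spry2 (1.56 ± 0.13), Fosl1 (1.29 ± 0.19) and Dusp6 (0.98 ± 0.14) rose, with 1 of the 2 other Dusp6 probe sets called lower. Fgfr1 (2.57 ± 0.57), Cdh1 (-0.86 ± 0.25), Vim (2.16 ± 0.72), Egr1 (-1.67 ± 0.45) and Mmp9 (1.42 ± 0.29) passed but lost their calls in 1, 3, 9, 4 and 1 of the 18 fits without 1 array. The adjusted p was 0.065 for Fgfr1 (then 1.40), 0.25 for Cdh1 (-0.55), 0.45 for Vim (1.09) and 0.093 for Egr1 without the library labelled NBTII-FGFR1 0 h replicate 1, and 0.052 for Mmp9 (then 0.93) without 48 h replicate 1. Krt8 (-0.37 ± 0.28), Fn1 (-0.39 ± 0.27), Plau (-0.51 ± 0.25) and Snai1 (-0.07 ± 0.16) did not pass. Among 35 mesenchymal and fibroblast markers 4 rose and 2 fell (3 and 2 adjusted over the list alone; median -0.04, mean 0.03, adjusted p = 0.96). The hyaluronan receptor gene Cd44 rose by 1.55 ± 0.16 and the transcription factor Zeb1 by 1.14 ± 0.18. Of 26 interferon response genes 12 rose and 1 fell (12 and 3 adjusted over the list alone; adjusted p = 0.0025, adjusted p = 0.15 with an estimated correlation). B2m, encoding the light chain of MHC class I, rose by 1.32 ± 0.16 and Ifi27 by 1.66 ± 0.18. Of 29 glycolysis and hypoxia response genes 12 rose and 2 fell (14 and 4 adjusted over the list alone; adjusted p = 0.0012, adjusted p = 0.16 with an estimated correlation). The hexokinase gene Hk2 rose by 1.53 ± 0.19. The 3393 calls (1659 higher, 1734 lower) became 2086 without the library labelled NBTII-FGFR1 0 h replicate 1, 1850 without 48 h replicate 1 and 2238 without 48 h replicate 2. Of the 93 named values past the threshold at 48 h, 76 stayed past it in each of the 18 fits, against 62 of 82 at 6 h, 18 of 61 at 24 h and 46 of 77 at 2 h.

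**Figure D2:**
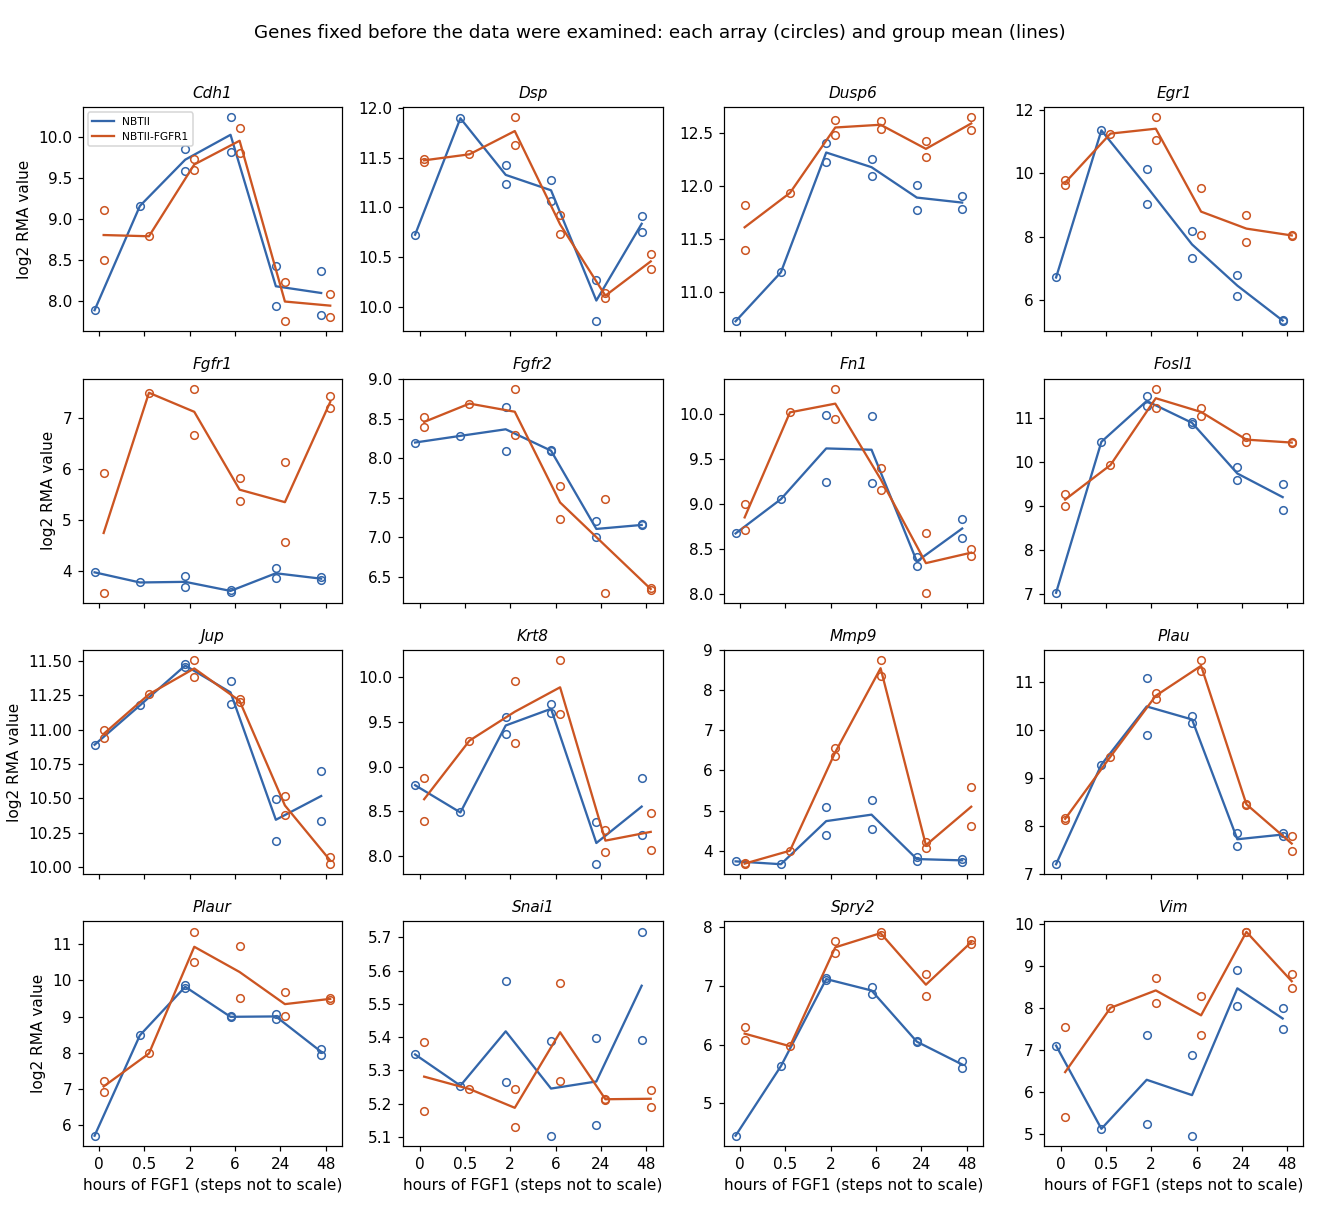
Log2 RMA value (y axis) of the 16 measured genes fixed before the data were examined, at 0 to 48 h of FGF1 (x axis, steps not to scale), in NBTII (blue) and NBTII-FGFR1 (orange): circles are single arrays and lines join group means. Fgfr1 stays between 3.58 and 4.05 in NBTII at 2 to 48 h, and at 0 h the library labelled NBTII-FGFR1 replicate 1 reads 3.57 and replicate 2 reads 5.92.

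Within NBTII-FGFR1, 48 h could be set against 2 h without the 0 h arrays (2 arrays against 2). Of the 2 h arrays, replicate 1 is a doubted one that lay towards 0.5 h, and the differences below average over it. Mmp10 rose by a further 5.81 ± 0.65, the calpain gene Capn8 (1387991_at) by 4.75 ± 0.34, Chac1, which degrades glutathione (1389573_at), by 3.93 ± 0.46, the cytokine gene Il24 (1368210_at) by 3.61 ± 0.49, Prl8a7 (1370227_at) by 3.28 ± 0.65 and the lipid droplet gene Plin2 (1382680_at) by 3.23 ± 0.23. Bcl2l11, encoding the pro-apoptotic protein Bim (1388742_at), fell by 3.93 ± 0.29, Krt5 by 3.81 ± 0.25, Fos by 3.72 ± 0.40, Krt15 (1372153_at) by 3.68 ± 0.50 and Plau (1398287_at) by 3.45 ± 0.24, and Slc1a3 fell by 3.49 ± 0.34 with 1 of its 2 other probe sets called higher. Cdh1 fell by 1.72 ± 0.25, Dsp by 1.31 ± 0.15, Fn1 by 1.66 ± 0.27 and Fgfr2 by 2.25 ± 0.29. Immediate-early genes fell, 21 of 30 with 2 higher (21 and 3 adjusted over the list alone; adjusted p = 7.5e-12, adjusted p = 0.057 with an estimated correlation). Desmosome genes fell, 4 of 7 with 0 higher (5 and 1 adjusted over the list alone; adjusted p = 0.0015, adjusted p = 0.15 with an estimated correlation). Of 20 adherens and tight junction genes 8 fell and 1 rose (8 and 2 adjusted over the list alone; adjusted p = 0.013, adjusted p = 0.36 with an estimated correlation). That list call was lost without both doubted arrays (adjusted p = 0.13). Replication genes fell, 23 of 26 with 0 higher (24 and 0 adjusted over the list alone; adjusted p = 6.6e-17, adjusted p = 0.11 with an estimated correlation). Limma called 1319 probe sets higher and 1488 lower, 2807 in all, but 1307 without 48 h replicate 1 and 1588 without 48 h replicate 2.

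In NBTII, which carries no transfected receptor, immediate-early, feedback and protease genes also rose by 2 h of FGF1 (2 arrays against 1). Fosl1 rose by 4.35 ± 0.23, Plaur by 4.12 ± 0.42, Plau by 3.28 ± 0.31, Spry2 by 2.67 ± 0.16, Egr1 by 2.87 ± 0.56, Dusp6 by 1.59 ± 0.17 and Cdh1 by 1.83 ± 0.30. Asprv1 rose by 4.43 ± 0.49, and the factor gene Wnt6 (1376063_at) fell by 1.48 ± 0.22 and Fry (1377011_at) by 2.23 ± 0.32. Of 30 immediate-early genes 15 rose and 0 fell (18 and 0 adjusted over the list alone; adjusted p = 6.1e-21, and adjusted p = 0.0075 with an estimated correlation). Of 14 feedback genes 7 rose and 0 fell, by the same counts adjusted over the list alone (adjusted p = 2.8e-07, and adjusted p = 0.022 with an estimated correlation). Of the growth factor and receptor kinase genes 8 of 42 rose and 1 fell (12 and 1 adjusted over the list alone; adjusted p = 2e-05, and adjusted p = 0.022 with an estimated correlation). Hbegf rose by 4.11 ± 0.37 and Areg by 3.36 ± 0.36. The proteolysis list (6 of 32 higher, 0 lower; 9 and 0 adjusted over the list alone) had an adjusted p of 9.3e-07 (adjusted p = 0.021 with an estimated correlation). Id2 (-2.70 ± 0.57), an inhibitor of bHLH transcription factors, lost its call without 2 h replicate 1 (adjusted p = 0.095). Mmp9 (adjusted p = 0.16), Fn1 (0.94 ± 0.33), Dsp (0.60 ± 0.18), Jup (0.58 ± 0.16), Krt8 (0.67 ± 0.34), Vim (-0.81 ± 0.89), Fgfr1 (-0.19 ± 0.69), Fgfr2 (0.17 ± 0.36) and Snai1 (0.07 ± 0.19) did not pass. Limma called 466 probe sets (310 higher, 156 lower), 248 without NBTII 2 h replicate 1, 759 without either NBTII-FGFR1 2 h array and 706 without both doubted arrays.

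At 6 h in NBTII (2 arrays against 1), adhesion genes rose and replication and cholesterol synthesis genes fell. Of 43 integrin, focal adhesion and actin genes 17 rose and 0 fell (21 and 0 adjusted over the list alone; adjusted p = 5.6e-12, and adjusted p = 0.011 with an estimated correlation). Flna, an actin crosslinker gene, and Vcl, encoding vinculin, rose by 1.17 ± 0.20 each. In the hemidesmosome and laminin-332 list 4 of 11 rose and 0 fell (9 and 0 adjusted over the list alone; adjusted p = 3.8e-08, adjusted p = 0.067 with an estimated correlation). Lama3 rose by 2.89 ± 0.28 and Itga6 by 1.15 ± 0.15. Replication genes fell, 12 of 26 with 0 higher (21 and 0 adjusted over the list alone; adjusted p = 2e-15, adjusted p = 0.067 with an estimated correlation). Mcm2 changed by -1.07 ± 0.18. Cholesterol synthesis genes fell, 8 of 19 with 0 higher (13 and 0 adjusted over the list alone; adjusted p = 1.6e-11, adjusted p = 0.16 with an estimated correlation). The squalene synthase gene Fdft1 (1367839_at) changed by -2.47 ± 0.37 and Dhcr7 by -1.71 ± 0.19. Mmp13 rose by 5.14 ± 0.63, Asprv1 by 4.51 ± 0.49, Fosl1 by 3.85 ± 0.23, Plaur by 3.29 ± 0.42, Plau by 3.01 ± 0.31, Spry2 by 2.48 ± 0.16, Cdh1 by 2.13 ± 0.30 and Dusp6 by 1.45 ± 0.17. The neuronal regeneration gene Nrep (-3.37 ± 0.79) and Id2 (-2.91 ± 0.57) lost their calls without NBTII 6 h replicate 1 (adjusted p = 0.14 and 0.064). Egr1 (1.04 ± 0.56), Mmp9 (1.17 ± 0.35), Fn1 (0.93 ± 0.33), Dsp (0.45 ± 0.18), Jup (0.38 ± 0.16), Krt8 (0.85 ± 0.34), Vim (-1.18 ± 0.89), Fgfr1 (-0.36 ± 0.69), Fgfr2 (-0.10 ± 0.36) and Snai1 (-0.10 ± 0.19) did not pass. The 936 calls (587 higher, 349 lower) became 404 without NBTII 6 h replicate 1.

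Fewer genes passed in NBTII at 24 and 48 h (2 arrays against 1 each). Each difference from 0 h here rests on the lone NBTII 0 h array, which none of the 18 fits left out. Fosl1 (2.70 ± 0.23 and 2.17 ± 0.23) and Spry2 (1.60 ± 0.16 and 1.22 ± 0.16) were still raised at both times. Mmp13 (4.29 ± 0.63), Plaur (3.30 ± 0.42) and Dusp6 (1.17 ± 0.17) were raised at 24 h. At 48 h the values of Mmp13 (3.55 ± 0.63), Plaur (2.32 ± 0.42) and Dusp6 (1.12 ± 0.17) passed, and were lost in 2 of the 18 fits each (adjusted p up to 0.11, 0.11 and 0.060 without 48 h replicate 2). At 24 h Mmp3 (2.71 ± 0.54, then 1.76), Krt15 (-3.88 ± 0.61) and Selenop, a selenium carrier (-2.75 ± 0.53), were lost without 24 h replicate 2 (adjusted p = 0.098, 0.063 and 0.16), and Nrep (-3.93 ± 0.79) in 4 fits (adjusted p up to 0.13). At 48 h Id2 (-2.86 ± 0.57), Krt15 (-2.80 ± 0.61) and the growth hormone receptor gene Ghr (-1.88 ± 0.41) were lost in 2, 12 and 10 fits (adjusted p up to 0.14, 0.27 and 0.19). Keratin genes fell at 24 h, 3 of 13 with 0 higher (5 and 0 adjusted over the list alone; adjusted p = 9.3e-05, adjusted p = 0.14 with an estimated correlation), and at 48 h, 4 of 13 with 0 higher, by the same counts adjusted over the list alone (adjusted p = 3.2e-05, adjusted p = 0.14 with an estimated correlation). Krt14 changed by -1.29 ± 0.16 at 48 h. Unfolded protein and amino acid response genes rose at 48 h, 5 of 34 over all genes and 33 adjusted over the list alone, with 0 lower (median 0.80, adjusted p = 2.3e-26, adjusted p = 0.082 with an estimated correlation). The other fixed genes did not pass at either time, Cdh1 at 0.29 ± 0.30 and 0.21 ± 0.30, Vim at 1.36 ± 0.89 and 0.64 ± 0.89, Dsp at -0.66 ± 0.18 and 0.11 ± 0.18, and Fgfr2 at -1.10 ± 0.36 and -1.04 ± 0.36 among them. The 149 calls at 24 h (90 higher, 59 lower) became 61 and 43 without the respective NBTII 24 h arrays, 89 without either NBTII-FGFR1 48 h array, 244 without either NBTII-FGFR1 2 h array, 226 without both doubted arrays and 280 with array weights. The 144 calls at 48 h (92 higher, 52 lower) became 53 and 12 without the respective NBTII 48 h arrays, 90 without either NBTII-FGFR1 48 h array, 270 without either NBTII-FGFR1 2 h array, 238 without both doubted arrays and 466 with array weights.

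Between 2 and 48 h in NBTII (2 arrays against 2), immediate-early, keratin and adhesion genes fell. Asprv1 fell by 4.56 ± 0.40, Egr1 (1368321_at) by 4.23 ± 0.45, the MYC antagonist gene Mxd1 (1376077_at) by 3.68 ± 0.51, Hbegf (1368983_at) by 3.64 ± 0.30, the nuclear receptor gene Nr4a3 (1369067_at) by 3.23 ± 0.42 and Plet1 (1374594_at) by 3.22 ± 0.55. Efhd1 (1376770_at) rose by 2.71 ± 0.33, the focal adhesion gene Tns3 (1388906_at) by 1.98 ± 0.30, the desaturase gene Fads3 (1372476_at) by 1.84 ± 0.24 and the carrier gene Slc25a33 (1373282_at) by 1.68 ± 0.18. Ezh1 (2.18 ± 0.40) and Dab2 (1.72 ± 0.42) passed but lost their calls in 1 and 2 of the 18 fits (adjusted p up to 0.053 without 48 h replicate 1 and 0.29 without 48 h replicate 2). Of 30 immediate-early genes 17 fell and 0 rose (19 and 0 adjusted over the list alone; adjusted p = 2.5e-20, and adjusted p = 0.0084 with an estimated correlation). Keratin genes fell, 7 of 13 with 0 higher (8 and 0 adjusted over the list alone; adjusted p = 2.8e-09, and adjusted p = 0.023 with an estimated correlation). Krt5 changed by -1.74 ± 0.25. Also, 11 of 43 integrin, focal adhesion and actin genes fell with 0 higher (17 and 1 adjusted over the list alone; adjusted p = 2.6e-08, and adjusted p = 0.021 with an estimated correlation). Of 9 FGF receptor and coreceptor genes 3 fell and 0 rose, by the same counts adjusted over the list alone (adjusted p = 0.0013, and adjusted p = 0.034 with an estimated correlation). The syndecan gene Sdc1 changed by -0.97 ± 0.11. Cdh1 fell by 1.62 ± 0.25 and Jup by 0.95 ± 0.13. Replication genes did not pass, with 0 of 26 called over all genes or adjusted over the list alone (median -0.11, adjusted p = 0.081). Limma called 378 probe sets higher and 419 lower, 797 in all, but 448 without 2 h replicate 1, 325 without 48 h replicate 1 and 225 without 48 h replicate 2.

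**Figure D3:**
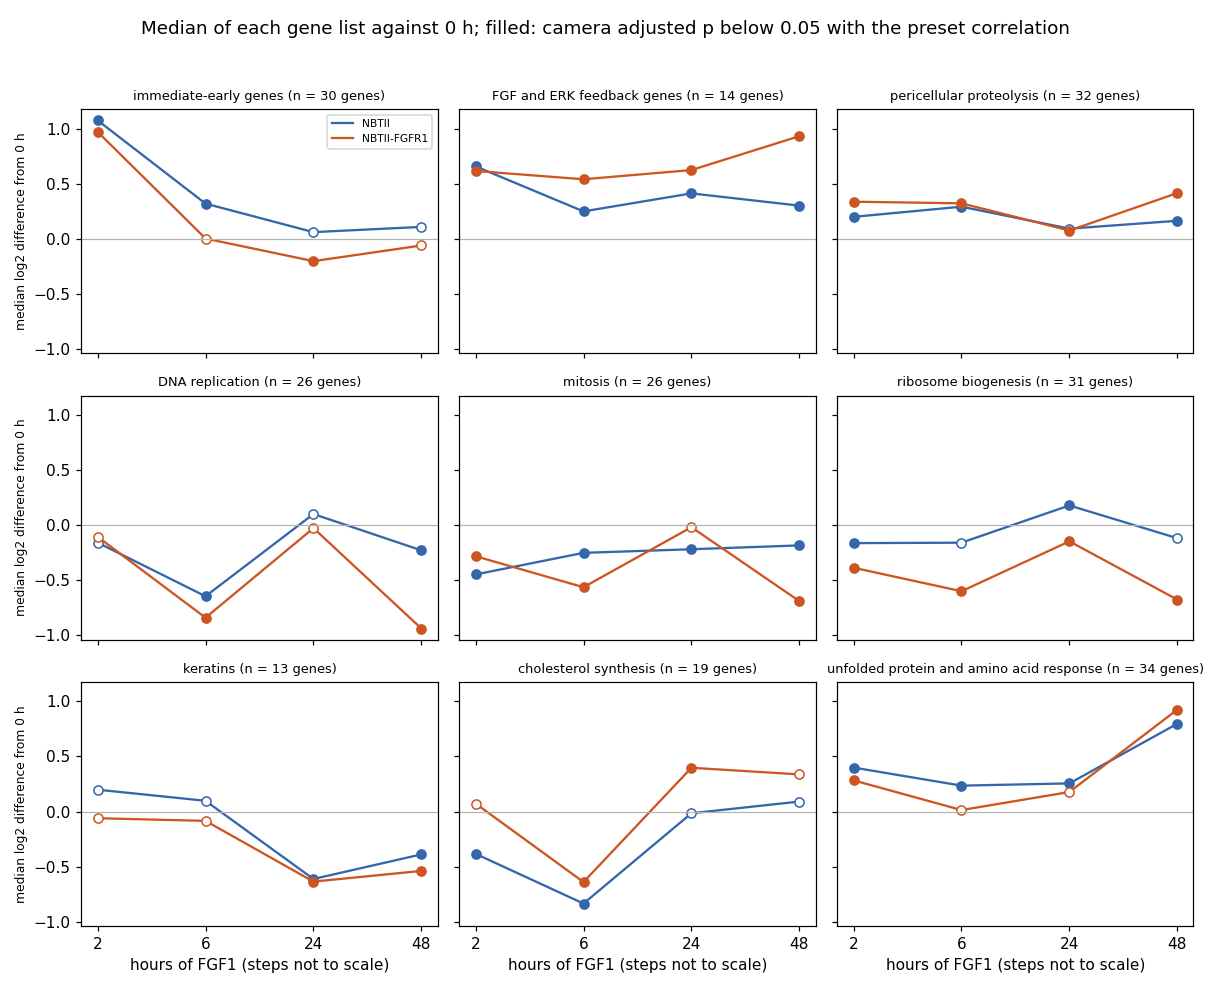
Median log2 difference from 0 h (y axis) of 9 gene lists at 2, 6, 24 and 48 h (x axis, steps not to scale) in NBTII (blue) and NBTII-FGFR1 (orange), with filled points where camera's adjusted p with the preset correlation is below 0.05. Replication genes lie at -0.84 in NBTII-FGFR1 and -0.64 in NBTII at 6 h, and at -0.94 and -0.23 at 48 h.

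Averaged over 2, 6, 24 and 48 h (8 arrays against 8), NBTII-FGFR1 exceeded NBTII in stromelysins and in genes of FGF signalling. Spry2 (1.74), Fosl1 (2.11) and Dusp6 (0.89) were already higher at 0 h, before FGF1, in the arrays labelled NBTII-FGFR1. Same-numbered arrays of a line deviated partly together between times (r up to 0.23 in NBTII and 0.35 in NBTII-FGFR1). The fit treats the 8 arrays of a line as independent, so the SEs of the mean over 2 to 48 h may be too small. Mmp10 was higher by 4.93 ± 0.33, Mmp3 by 4.37 ± 0.22, Fgfr1 by 2.55 ± 0.28, Mmp9 by 1.76 ± 0.14, Tnfaip6, a hyaluronan-binding protein gene (1371194_at), by 1.59 ± 0.23 and the lysophosphatidic acid receptor gene Lpar1 (1370048_at) by 1.58 ± 0.15. The Fgfr1 value is a lower bound, since the 8 NBTII arrays (3.58 to 4.05) lie below the lower quartile. Igfbp5 (1370960_at) was lower by 3.42 ± 0.46 (-3.42), the sodium pump regulator Fxyd2 (1387799_at) by 2.95 ± 0.32 (-2.95), Fam13c (1374542_at) by 1.37 ± 0.17 (-1.37), Ccnq (1390730_at) by 1.31 ± 0.17 (-1.31), the transporter gene Slco4a1 (1389067_at) by 1.24 ± 0.19 (-1.24) and the matrix gene Sparc (1367562_at) by 1.19 ± 0.19 (-1.19). Egr1 (1.84 ± 0.23), Vim (1.56 ± 0.36), Spry2 (1.15 ± 0.07), Plaur (1.04 ± 0.17), Fosl1 (0.58 ± 0.09) and Dusp6 (0.46 ± 0.07) were higher in NBTII-FGFR1, and Plau (0.47 ± 0.13) lost its call in 2 of the 18 fits (adjusted p = 0.059 without NBTII-FGFR1 48 h replicate 1 and 0.052 without NBTII 24 h replicate 2). Of 14 feedback genes 7 were higher and 0 lower (8 and 2 adjusted over the list alone; adjusted p = 1.4e-05, adjusted p = 0.10 with an estimated correlation). Of 32 proteolysis genes 13 were higher and 1 lower (16 and 5 adjusted over the list alone; adjusted p = 1.2e-05, adjusted p = 0.10 with an estimated correlation). Of 26 mitosis genes 13 were lower and 0 higher (18 and 0 adjusted over the list alone; adjusted p = 3.1e-07, adjusted p = 0.22 with an estimated correlation). Ccnb2 differed by -0.49 ± 0.06. Cdh1 (-0.12 ± 0.12), Dsp (-0.06 ± 0.07), Jup (-0.11 ± 0.07), Krt8 (0.03 ± 0.14), Fn1 (-0.03 ± 0.13), Fgfr2 (-0.36 ± 0.15) and Snai1 (-0.11 ± 0.08) did not pass. Of 29 leukocyte markers 1 was higher and 2 lower (0 and 1 adjusted over the list alone; adjusted p = 0.028, adjusted p = 0.41 with an estimated correlation). The actin-bundling gene Lcp1, which carcinoma lines also express, differed by -0.92 ± 0.09. Of 21 endothelial markers 1 was higher and 2 lower, by the same counts adjusted over the list alone (adjusted p = 0.29). The VEGF receptor gene Flt1 was higher by 0.67 ± 0.17. Of 19 urothelial differentiation genes 2 were higher and 3 lower, by the same counts adjusted over the list alone (median -0.07, mean -0.00, adjusted p = 0.52). Limma called 2611 probe sets, 1323 higher and 1288 lower, of which 80 differed by over 1 on the log2 scale.

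At 0 h, before FGF1 (2 arrays against 1), limma called 73 probe sets between the lines, 58 higher and 15 lower in the arrays labelled NBTII-FGFR1. Fos was higher by 4.38 ± 0.49, Fosl1 by 2.11 ± 0.23 and Spry2 by 1.74 ± 0.16. Of 30 immediate-early genes 6 were higher and 0 lower (11 and 0 adjusted over the list alone; adjusted p = 3.1e-11, adjusted p = 0.062 with an estimated correlation). Egr1 (2.99 ± 0.56), Klk6 (2.11 ± 0.40), the binding protein gene Igfbp7 (-1.64 ± 0.32), the calpain gene Capn3 (-1.59 ± 0.30) and the isocitrate dehydrogenase gene Idh1 (-1.59 ± 0.23) passed, but lost their calls in 8, 8, 8, 5 and 1 of the 18 fits, with adjusted p up to 0.20, 0.27, 0.30, 0.30 and 0.085 without NBTII-FGFR1 0 h replicate 2. Directions here rest on 1 array of NBTII and on the library labelled NBTII-FGFR1 0 h replicate 1. The count was 3 without 0 h replicate 2, 155 without either NBTII-FGFR1 2 h array, 35 without either NBTII 24 h array, 25 without either NBTII 48 h array, 26 without either NBTII-FGFR1 48 h array, 206 without both doubted arrays and 190 with array weights. With only the 3 arrays of 0 h, limma called 0 (2096 at an unadjusted p under 0.05), and the adjusted p was 0.069 for Fos, 0.078 for Fosl1 and 0.098 for Spry2.

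The 2 lines' responses were set against each other directly. Between 2 and 48 h, Capn8 rose more in NBTII-FGFR1 than in NBTII by 4.66 ± 0.48. The change in Spry2 differed by 1.55 ± 0.18. In NBTII it lay 2.67 above 0 h at 2 h and 1.22 at 48 h, and in NBTII-FGFR1 1.47 and 1.56. These start from unlike 0 h levels, 4.45 in NBTII and 6.19 in NBTII-FGFR1. The NBTII level lies below the lower quartile of its array (4.46), so 2.67 and 1.22 are lower bounds. The lines' differences from 0 h therefore do not rank their Spry2 responses. Capn8 and Spry2 were the 2 of the 39 named values past the threshold whose calls held in each of the 18 fits without 1 array. Replication genes differed downward in NBTII-FGFR1, 4 of 26 with 0 the other way (19 and 0 adjusted over the list alone; median -0.69, adjusted p = 1.9e-15, adjusted p = 0.10 with an estimated correlation). Mitosis genes differed the same way, 7 of 26 with 0 the other way (17 and 0 adjusted over the list alone; median -0.71, adjusted p = 1.2e-13, adjusted p = 0.10 with an estimated correlation), and their median in NBTII was 0.24 above its 2 h level (adjusted p = 0.012, adjusted p = 0.45 with an estimated correlation). Mmp10 differed by 5.82 ± 0.92, Il24 by 3.88 ± 0.70, Bcl2l11 by -2.90 ± 0.41, Slc1a3 by -2.89 ± 0.48 and Fam111a (1371970_at) by -2.16 ± 0.48, calls that were lost in 3, 4, 2, 4 and 12 of the 18 fits (adjusted p up to 0.075, 0.12, 0.052, 0.086 and 0.20). The 286 calls (131 higher, 155 lower) moved by over 1.5 times in 14 of the 18 fits. For NBTII they came to 5 and 78 without 48 h replicates 1 and 2, 29 and 595 without 2 h replicates 1 and 2, 184 without either 6 h array and 171 without either 24 h array. For NBTII-FGFR1 they came to 88 and 1591 without 2 h replicates 1 and 2, 11 and 58 without 48 h replicates 1 and 2, 179 without either 0 h array, and 59 without both doubted arrays. They came to 179 with only the arrays compared and 135 with array weights.

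The F test of line by time over 2 to 48 h called 70 probe sets, a count that also moved by over 1.5 times in 14 of the 18 fits. Capn8 and Spry2 kept their calls in the 48 h against 2 h difference, while the F count came to 6 and 28 without NBTII 48 h replicates 1 and 2, 13 and 355 without NBTII 2 h replicates 1 and 2, 20 and 35 without NBTII 6 h replicates 1 and 2, and 37 without NBTII 24 h replicate 2. It came to 1062 without NBTII-FGFR1 2 h replicate 2, 150 and 42 without NBTII-FGFR1 6 h replicates 1 and 2, 11 and 15 without NBTII-FGFR1 48 h replicates 1 and 2, and 36 without either NBTII-FGFR1 0 h array. It was 19 without both doubted arrays, 43 without the probe sets below the median level, 36 with only the arrays compared and 150 with array weights. Measured from each line's own 0 h and averaged over 2 to 48 h, the responses differed at 34 probe sets (13 higher, 21 lower in NBTII-FGFR1), at 0 by limma without the library labelled NBTII-FGFR1 0 h replicate 1 (1315 at an unadjusted p under 0.05, against 1650 with it), and at 1 without 0 h replicate 2. They differed at 100 and 84 without NBTII-FGFR1 2 h replicates 1 and 2, 54 without its 6 h replicate 1, 55 without its 24 h replicate 1, 18 without either of its 48 h arrays, 21 without NBTII 48 h replicate 1, 13 without both doubted arrays and 102 with array weights. Across genes, which are not independent replicates, the responses of the 2 lines correlated at r = 0.63 at 2 h (Spearman 0.41), 0.62 at 6 h (0.46), 0.49 at 24 h (0.34) and 0.51 at 48 h (0.38), and at r = 0.51 for 48 h against 2 h (Spearman 0.34), or 0.35 without NBTII-FGFR1 2 h replicate 2. With 1 array from each of those 4 groups, r lay between 0.16 and 0.69 over the 16 choices (SD 0.15). Of the 936 NBTII calls at 6 h, 691 were called in the same direction in NBTII-FGFR1 and 14 in the opposite one. Independent lists would share 96.7. The 0 h arrays of both lines had higher poly-A spikes. A labelling difference they share could raise this overlap and the correlations from 0 h. Between 2 and 48 h, which uses no 0 h array, 467 of 797 NBTII calls were shared in direction and 6 opposite. There, independent lists would share 70.7.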

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

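The tests of the 3 patterns weighed in the next 3 paragraphs were chosen after the results were seen, and some of their bounds were rewritten after the test values were known; the splits of the samples were planned before.

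The library labelled NBTII-FGFR1 0 h replicate 1 read 3.57 in Fgfr1, at the NBTII level. A wrong label is a candidate explanation, since its median position over 115 probe sets that part the lines was -0.0045, among the NBTII arrays. A swap with the NBTII 0 h array needs that array to lie on the other side, and it lay at -0.2017. Loss of Fgfr1 expression in the transfected culture cannot be told apart from a wrong label: without the Fgfr1 probe sets the position was -0.0041, but the other separating genes may follow the receptor. In Fos the library (9.52) lay nearer to replicate 2 (9.03) than to NBTII at 0 h (4.90). Its whole profile also correlated best with replicate 2 (r = 0.995). Neither decides the label, since neither parts the lines in every array. Over 2 to 48 h, Fos overlapped between NBTII (4.77 to 7.08) and NBTII-FGFR1 (4.98 to 9.78). Whole profiles could pair across the lines: NBTII-FGFR1 at 0.5 h correlated best with NBTII at 0.5 h (r = 0.990).

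NBTII-FGFR1 2 h replicate 1 correlated best with the NBTII 0.5 h array. Its partner correlated best with NBTII 2 h replicate 2 (r = 0.993). An earlier harvest of replicate 1 is a candidate explanation. Its position was read on a scale from its partner (0) to the NBTII-FGFR1 0.5 h array (1). Over 181 probe sets that part 0.5 h from 2 h in NBTII, the median was 0.6449 (quartiles 0.20 and 0.94), and 108 were nearer to 0.5 h. Only 88 of the 181 parted the 2 ends of the scale the same way by over 1 log2. Over those 88 the median was 0.6421 and 56 were nearer to 0.5 h, and on the others the position has no clear meaning. RNA degradation would raise the 3' to 5' gap of beta-actin, which was 0.4889, inside the 0.203 to 0.57 of the other arrays. The wrong line was argued against by a position of 0.5817 on the probe sets that part the lines at 6 to 48 h, above every NBTII array of 2 to 48 h (up to 0.34). A faster or slower response of the same culture was not tested.

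The bacterial poly-A spikes were higher in the 3 arrays of 0 h than in the 18 later ones, with a gap of 0.4658 between the lowest of the former and the highest of the latter. Separate labelling of the 0 h arrays cannot be told apart from the time itself, since no 0 h array lies outside that set. Less mRNA per total RNA before FGF1 stays open too: the 0.5 h arrays already averaged 5.9354, within the range of the later arrays, and the mRNA content was not measured. The hybridisation spikes, added after labelling, also averaged higher at 0 h (9.72 against 9.45), which mRNA content alone would not give, but 1 later array (9.71) lay above the lowest of 0 h (9.66). No biological explanation was tested.

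The line difference over 2 to 48 h called 2611 probe sets. Of 100 splits that exchange line labels within times, drawn from 648, 1 gave as many, the real one, and the highest other gave 922. Exchange of labels alone thus did not reach the real count. Mixing the lines puts their difference into the spread and lowers the other counts, so the size of the gap is no measure of chance. The splits also cannot tell the lines from cultures or batches that differ with them. For the F test of line by time, which called 70, 15 of 100 splits gave as many, the real one included, and the highest other gave 1012. Splits that exchange the lines at some times turn the line difference into one that varies with time, a structure of the samples, so they do not test chance for that count, which stays open.

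By tests of the difference itself, the lines differed in their change from 2 to 48 h at 286 probe sets, in their mean response from 0 h at 34 and over all 4 times at 70. Between 2 and 48 h the difference, NBTII-FGFR1 minus NBTII, was 5.82 for Mmp10, 4.66 for Capn8, 3.88 for Il24, -2.90 for Bcl2l11, -2.89 for Slc1a3, -2.16 for Fam111a, 1.55 for Spry2 and 1.17 for Fosl1. In the mean response from 0 h it was 5.18 for Mmp10, 4.59 for Mmp3 and 1.56 for Tmsb4x (1387883_a_at). It was -3.30 for Fos, -2.70 for Klk6, -2.06 for Fst (1387843_at) and -1.53 for Fosl1. Fos and Fosl1 started higher in the arrays labelled NBTII-FGFR1, by 4.38 and 2.11 at 0 h. Their negative values therefore do not mean lower levels under FGF1, and Fosl1 was higher in NBTII-FGFR1 over 2 to 48 h. Of the 9 named values of this comparison, 0 kept the call by limma in every fit without 1 array.

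List medians also differed. Between 2 and 48 h they were 0.36 for FGF and ERK feedback, 0.23 for proteolysis, -0.69 for DNA replication, -0.71 for mitosis, 0.23 for integrins, focal adhesion and actin, 0.21 for cytokines, 0.19 for interferon response and -0.34 for ribosome biogenesis. In the mean response from 0 h they were -0.18 for immediate-early genes, -0.30 for keratins, 0.089 for proteolysis, -0.28 for DNA replication, -0.61 for hemidesmosome and laminin-332, 0.14 for cytokines, 0.25 for cholesterol synthesis and -0.31 for ribosome biogenesis. With an estimated correlation, 0 of these 16 camera calls held, and the lowest adjusted p was 0.10.

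Among control probe sets, which the comparisons leave out, values are set against the mean of the 3 arrays of 0 h of both lines. In NBTII-FGFR1, 5S rRNA was 1.67 higher at 48 h but lower at 0.5, 2, 6 and 24 h (-0.41, -0.86, -0.86 and -0.69), the 3' hexokinase probe set 1.11 at 6 h and 1.03 at 48 h, and the 5' hexokinase probe set 1.01 at 48 h. In NBTII, 5S rRNA lay between -0.33 (0.5 h) and 0.66 (2 h), the 3' hexokinase probe set 0.93 at 6 h and 0.93 at 48 h, and the 5' hexokinase probe set 0.97 at 48 h. No group has 4 or more samples, so the test for a sample far from the others of its group applied to 0 groups.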

How the results depend on the processing

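The alternative without both doubted arrays was added after the data were seen; the others were chosen before. No result reversed its direction, and the cause was not tested for any value below. Fewer arrays of a comparison give it less precision. An array outside a comparison enters it only through the shared spread, so leaving it out changes the count but not the estimates. The count can then rise, as the spread differed between groups. The NBTII-FGFR1 arrays differed most from each other at 2 h (SD 0.36 across probe sets) and least at 48 h (0.165).

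By replicate number, deviations correlated above 0.1 in 15 of 36 pairs of groups (median r = 0.02). These held all 6 pairs among NBTII 2 to 48 h (0.1149 to 0.2323) and all 3 among NBTII-FGFR1 2, 6 and 24 h (0.174 to 0.3478); NBTII-FGFR1 0 h reached 0.05 and 48 h 0.028. The labels do not say what a number shares, so the planned fit without a block was kept. With the block the line difference at 0 h came to 125 probe sets (73 without) and the response difference to 115 (34 without). Without the probe sets below the median level the F test called 43. The Spearman correlation of the 48 h against 2 h responses was 0.3364, against a Pearson r of 0.5085. With only the arrays a comparison is about, the calls were 968 (NBTII-FGFR1 2 h), 566 (24 h), 147 (0.5 h over both lines), 179 (line by time, 48 h against 2 h), 36 (F test) and 0 by limma for the line difference at 0 h (2096 at an unadjusted p under 0.05). Array weights gave 766, 1715 and 626 for NBTII-FGFR1 2, 24 and 0.5 h, 280 and 466 for NBTII 24 and 48 h, 653 for 0.5 h over both lines, 190 for the lines at 0 h, 135 for line by time, 102 for the response difference and 150 for the F test. Without both doubted arrays the same results came to 686, 379 and 116, 226 and 238, and, from the lines at 0 h on, 206, 59, 13 and 19, with 706 for NBTII 2 h. With an estimated correlation 21 of 368 list tests were called, against 168 with the preset one; fry called 148, among them 130 of the 168.

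With each array left out in turn, the lowest and highest counts for NBTII-FGFR1 were 518 and 1753 (2 h), 1898 and 3825 (6 h), 114 and 1357 (24 h), 1850 and 3860 (48 h), 49 and 502 (0.5 h), and 1307 and 3106 (48 h against 2 h). For NBTII they were 248 and 759 (2 h), 404 and 1235 (6 h), 43 and 244 (24 h), 12 and 270 (48 h), and 225 and 1117 (48 h against 2 h). They were 184 and 664 for 0.5 h over both lines, 3 and 155 for the lines at 0 h, 5 and 1591 for line by time, 6 and 1062 for the F test, and 0 (1315 at an unadjusted p under 0.05 by limma) and 100 for the response difference. The correlation ranged from 0.3548 to 0.6012, and over the 16 choices of 1 array from each of its 4 groups from 0.1645 to 0.6908 (SD 0.153). The line difference over 2 to 48 h (1795 to 3218) and the list tests (164 to 172) stayed within 1.5 times.

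Of the named values, 1423 fell short of the threshold and 411 newly passed it over the 18 fits without 1 array, with 27092 on the same side. Those that fell short were 39 with array weights, 107 with own arrays only, 31 with repeated quantile normalization, 10 with the block, 56 with trend and robust eBayes, 136 without both doubted arrays and 0 without probe sets below the median level. Those that newly passed were 93, 34, 23, 55, 8, 32 and 22, in the same order. Without the probe sets below the median level, named values on those probe sets were not tested. They could thus neither fall short nor newly pass.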

Other observations

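The comparison of NBTII at 0.5 h with NBTII at 0 h has 1 array on each side and no test; it was read after the data were seen. Dusp1 read 10.98 at 0.5 h and 5.87 at 0 h, Fosl1 10.46 and 7.04, and Plaur 8.48 and 5.70. At 0 h, Vim read 7.11 in NBTII, 5.41 in the library labelled NBTII-FGFR1 replicate 1 and 7.55 in replicate 2, and Egr1 read 6.71, 9.79 and 9.63.

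Glycolysis and hypoxia response genes rose in both lines at 2 h. Of 29 glycolysis and hypoxia response genes 10 rose and 0 fell in NBTII-FGFR1 (10 and 1 adjusted over the list alone; adjusted p = 5.2e-06, adjusted p = 0.073 with an estimated correlation) and 5 rose and 0 fell in NBTII (9 and 0 adjusted over the list alone; adjusted p = 1.6e-06, adjusted p = 0.051 with an estimated correlation). Hmox1, encoding heme oxygenase 1, rose by 3.02 ± 0.27 and 3.05 ± 0.33, and Ndrg1 by 2.62 ± 0.27 and 2.36 ± 0.33. Ptgs2, which makes prostaglandins, rose by 2.24 ± 0.25 and 2.47 ± 0.30.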
